A study of Mus musculus with 8 samples.

How the data were processed

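The series holds 8 sequencing libraries from mouse retina on day 7 after injury, 4 labelled as microglia and 4 as infiltrating macrophages. Each was grouped by its tissue subtype in the labels and keeps the number in its title, 1 to 4 and 5 to 8. The labels name the same genotype, strain background, age and time point for every library and give no sequencing batch. Per the labels' protocols, libraries were made with an Illumina mRNA-seq sample preparation kit from RNA extracted with Sepazol reagent, and they were sequenced on an Illumina HiSeq instrument. Titles of the microglial libraries start with cont and those of the macrophage libraries with GFP, but the genotype in the labels names no GFP allele. What GFP marks and how the cells were sorted are not given in the sources used here.

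Per the submitters' processing notes, bcl2fastq 1.8.4 and Cufflinks 2.1.1 were used with the mm9 genome build. The aligner, its settings and the gene annotation are not given in the sources used here. Each deposited table, per the file headers, holds for each gene an FPKM estimate made by the authors, with the bounds of its confidence interval, a status and a locus. The tables list 23021 rows for 22558 symbols, of which 463 rows repeat a symbol. The status was FAIL for 9 symbols in 1 or more libraries, where the value is 0, and these symbols were left out: Atp7a, Canx, Ccdc93, Cnbp, Cnot1, Gab2, Prkd3, Slc38a10 and 4930513N10Rik. A value of exactly 0 can be a failed estimate, since genes with at least 20 FPKM in the other libraries were listed at 0 in microglia 2 (1 gene) and microglia 3 (1 gene). Such genes are described as listed at 0, with no fold. Between 927 and 1960 rows per library have an FPKM outside their own interval, and the intervals were not used. No 2 libraries held identical values.

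FPKM are not counts, and no count test was run. FPKM removes differences in depth and transcript length but not in composition, so a few very abundant transcripts lower all others: the 10 highest genes took between 14.3% and 21.1% of the FPKM sum. MicroRNA and snoRNA symbols took between 4.67% and 10.9%. FPKM of very short transcripts is unstable, and the rule for named genes leaves them out of its largest changes. Estimates for near-identical genes depend on how Cufflinks divided shared reads, which concerns Ly6c1 and Ly6c2, Hspa1a and Hspa1b, and the Ifi200 genes. Strand is not stated, so overlapping antisense genes cannot be told apart. For genes with a single annotated transcript of at least 800 bases, FPKM was multiplied by transcript length less an assumed fragment length of 150. Depth was estimated by taking the most frequent low product, sought within a fixed range, as 1 fragment. It came to 11.6, 20.2, 19.1, 20.9, 24.5, 21.6, 23.2 and 22.1 M fragments in libraries 1 to 8, at which 1 fragment on a transcript of 2 kb equals between 0.02 and 0.043 FPKM. These are approximate and no test used them.

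Rows sharing a symbol were summed. Genes with at least 1 FPKM in at least 4 of the 8 libraries entered the test (9352 genes). The comparison used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend in the empirical Bayes step, no covariate, a two-sided test and Benjamini-Hochberg adjustment; genes with an adjusted p below 0.05 are said to be called. Fold changes are macrophages minus microglia on the log2(FPKM + 1) scale, which understates the change of low genes, and are given with their standard errors. Gene lists were tested with camera in limma at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists with at least 3 tested members, and again with the correlation estimated per list and with fry, which tests a list by itself. With an estimated correlation 0 of the 20 called lists remained called, and fry called 5, those of microglial identity, neutrophils, MHC class II, monocytes and alternative activation. Sums and tables used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

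Before the data were examined, the test, the filter, 33 gene lists, the alternatives and the rule for named genes were fixed. The lists cover macrophage biology, other cells of retina and blood, and RNA quality, and no gene is in more than 1 of them; 31 have tested members. Named genes are 7 anchors (Tmem119, P2ry12, Sall1, Cx3cr1, Ccr2, Ly6c2 and Apoe); the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 FPKM in the higher population, no overlap between libraries and a symbol that is not a clone, predicted gene or small RNA; and in each list up to 3 called members with the highest mean FPKM, or the most abundant tested member where none was called. This named 65 genes, 52 of them called. Itgax, Timp2, Ly6c1, Ccr7, Ccl22, Ifi47, the Y-linked, Xist and haemoglobin genes, and the genes of the Ifi200 group were named after their values were seen.

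The limma step was tested on 10 simulated data sets of this comparison's 9352 genes, with 200 genes changed in each. It found 0.8% of genes changed by 1 on the log2 scale, 24.0% of those changed by 2, 67.4% of those changed by 3 and 84.4% of those changed by 4. Of its calls, 4.72% were unchanged genes, where the further genes of the shifted list described below count as changed. Changed genes were drawn only from those with a mean log2(FPKM + 1) above 3, so recovery of lower genes was not measured. Camera found a shifted list in 10 of 10 simulations and called 0 of 200 unchanged lists. Simulated genes varied independently of each other, whereas the estimated correlation in the real lists reached 0.79 (ribosomal proteins). Neither the 4.72% nor the 0 of 200 therefore measures false calls in these data. Coordinates are those of the deposited tables on mm9 with 1 added to each start, since a start raised by 1 equals the gene's start in GENCODE vM1 on the same assembly for 48.2% of genes, against 3.0% as written; the genes given with coordinates are annotated there as protein coding, and values cover whole genes.

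Alternatives changed the pseudocount, the filter, the scaling between libraries, limma's spread estimate, library weights, the treatment of repeated symbols and the test (an exact permutation over the 70 assignments, whose smallest two-sided p is 0.0286), and left out each library in turn. Chosen after seeing the data were fits without microglia 2 and 3 or without microglia 2 and macrophage 7, without small RNA and LOWDATA symbols, with failed symbols kept at 0, and with a term for Y-linked expression, which is 1 where Ddx3y, Eif2s3y, Kdm5d and Uty sum to 5 FPKM or more.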

Results

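Messenger RNA of macrophages in the injured mouse retina was profiled in 8 sequencing libraries, 4 of microglia, the resident macrophages of neural tissue, and 4 of macrophages that had infiltrated the retina. All mice carried Msi1-CreERT2, a tamoxifen-inducible Cre recombinase, together with R26R-DTA, a Cre-dependent allele of diphtheria toxin A that kills the cells in which it is switched on. Retinas were taken on day 7 after injury from mice of about 5 months on a mixed C57BL/6 and 129 background. The comparison asked how the 2 populations differed in gene expression at that time. The labels number the microglial libraries 1 to 4 and the macrophage libraries 5 to 8, and the same numbers are used here. Nothing in the labels says whether the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

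Values were deposited as FPKM, fragments per kilobase of transcript scaled to library size, for 22558 gene symbols. FPKM summed to between 296110 and 392952 in microglia and between 207154 and 512101 in macrophages. A depth estimated from the most frequent low value was 11.6 M fragments in microglia 1 and between 19.1 and 24.5 M in the other libraries. Microglial libraries held 8142 ± 1533 genes at 1 FPKM or more, and macrophage libraries 9675 ± 665 (SD, n = 4 each). Microglia 2 held the fewest, 5995. Across genes, log2(FPKM + 1) correlated at a mean Pearson r of 0.861 between macrophage libraries (6 pairs, 0.812 to 0.919), 0.755 between microglial libraries (6 pairs, 0.679 to 0.863) and 0.736 between populations (16 pairs, 0.629 to 0.832). These correlations are across genes, which are not independent replicates. The first principal component (40.7% of variance) set microglia 2 at -132 against -37.0 to 81.2 for the other libraries, and the second (19.9%) set microglia 3 at 97.7.

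The microglial libraries were not alike in transcripts that mark the animals or blood behind them. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 25.8, 11.7 and 16.5 FPKM in microglia 1, 2 and 3, but to 0.0533 in microglia 4 and to between 0.0107 and 1.97 in the macrophage libraries. Xist, the RNA that silences an X chromosome in female cells, stood at 4.78 FPKM in microglia 4 and between 4.84 and 7.94 in macrophages, and below 0.001 in microglia 1 to 3. Haemoglobin transcripts summed to 215, 227 and 3211 FPKM in microglia 1, 2 and 3, to 1.16 in microglia 4 and to between 0.804 and 26.7 in macrophages. By Y-linked and Xist RNA, microglia 1 to 3 read as male, and microglia 4 and the macrophage libraries as female. The labels do not give sex, and the 1.97 FPKM of Y-linked RNA was in macrophage 7. This split runs partly along the comparison, since microglia 4 is the only microglial library on the macrophage side of it. Counts from a fit with a term for Y-linked expression, chosen after seeing the data, therefore stand beside each gene list; that fit in effect sets microglia 4 against the 4 macrophage libraries.

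Genes higher in infiltrating macrophages than in microglia included the antigen-presenting genes of MHC class II and markers of monocyte origin, and those lower included Sparc, Cst7 and Sall1. Cd74, the invariant chain that escorts class II molecules, averaged 5288 ± 2218 FPKM in macrophages and 62.7 ± 51.8 in microglia (SD, n = 4 each). Ly6c2, a surface antigen of inflammatory monocytes, averaged 175 ± 216 against 0.445 ± 0.477 FPKM. Sparc, which encodes a secreted matrix glycoprotein, averaged 492 ± 233 FPKM in microglia and did not exceed 0.242 in any macrophage library. Cst7, the cysteine protease inhibitor cystatin F, averaged 777 ± 240 FPKM in microglia and 8.66 ± 8.07 in macrophages.

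Of 9352 genes tested with limma, 219 passed an adjusted p of 0.05, 154 of them higher and 65 lower in macrophages, and 1402 had an unadjusted p below 0.05. The 2 populations did not overlap in 202 of the 219, nor in 7.6% of all tested genes, where chance gives 2.86%. Among the called genes, 13 were listed at 0 in every microglial library and 2 in every macrophage library. Calls fell to 119 without macrophage 8 (84 higher, 35 lower) and to 122 without macrophage 5 (82 and 40), and without macrophage 6 there were 78 higher and 79 lower. With the term for Y-linked expression, 19 of the 219 genes were called (14 higher, 5 lower), 332 genes had an unadjusted p below 0.05, and 2 of the 219 changed sign. The tested genes had a median log2 fold change of 0.37, which moved to 0.63 when libraries were rescaled to an equal sum, 0.27 after upper-quartile scaling, 0.17 after median-of-ratios scaling and -0.03 after quantile normalization. The excess of higher calls (70.3%) fell to 59.5%, 55.3% and 53.4% under the last 3 of these scalings. No gene among the 219 changed sign under these 4 scalings. Left-out libraries also moved the median, to 0.22 without microglia 2, 0.17 without microglia 2 and 3, 0.19 without macrophage 6 and 0.56 without macrophage 7. The share of higher calls in these fits was 64.8%, 64.6%, 49.7% and 76.7%. Without any other single library the median lay between 0.34 and 0.44.

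**Figure D1:**
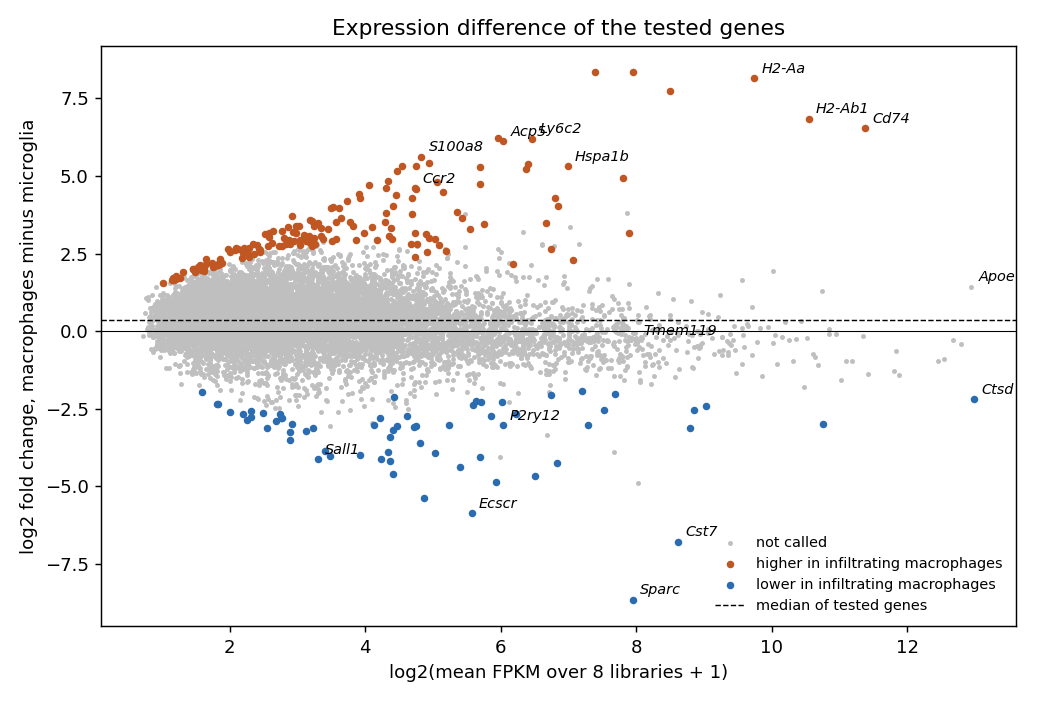
Log2 fold change (macrophages minus microglia, on the log2(FPKM + 1) scale) of each of the 9352 tested genes against the log2 of its mean FPKM + 1 over the 8 libraries. Called genes are coloured by direction, 154 higher and 65 lower in infiltrating macrophages; the dashed line is the median of 0.37.

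The genes fixed in advance as markers of resident microglia fell in part. Of 20 tested members of that list, 7 were called lower in macrophages and 0 higher (12 lower and 0 higher adjusted over the list alone), with a median log2 fold change of -1.42. Sall1, a transcription factor of microglial identity, stood between 8.62 and 26.8 FPKM in microglia, was listed at 0 in 3 macrophage libraries and stood at 0.0352 in macrophage 7 (log2 fold change -4.12 ± 0.66 SE, adjusted p = 0.000531). P2ry12, a purinergic receptor of microglial processes, averaged 114 ± 28.2 FPKM in microglia and 15.4 ± 10.5 in macrophages (-3.03 ± 0.56, adjusted p = 0.00254). Gpr34, a G protein-coupled receptor, averaged 125 ± 70.4 against 22.8 ± 20.3 FPKM (adjusted p = 0.0218), a call lost without microglia 1 or 4 or macrophage 5 or 8. Tmem119, a transmembrane marker of microglia, averaged 273 ± 72.6 FPKM in microglia and 236 ± 106 in macrophages (-0.29 ± 0.48, adjusted p = 0.817), and the fractalkine receptor Cx3cr1 103 ± 35.1 against 62.8 ± 39.0 (adjusted p = 0.483): neither difference passed the test. The list as a set was lower (camera adjusted p = 1.67e-23), and that call was lost with an estimated correlation (adjusted p = 0.0791, the highest of 23 alternatives). With the term for Y-linked expression 2 members were called lower at a list median of -1.57, with Sall1 at -4.22 and P2ry12 at -2.68 (not called), and without microglia 2 and 3, 8 were.

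**Figure D2:**
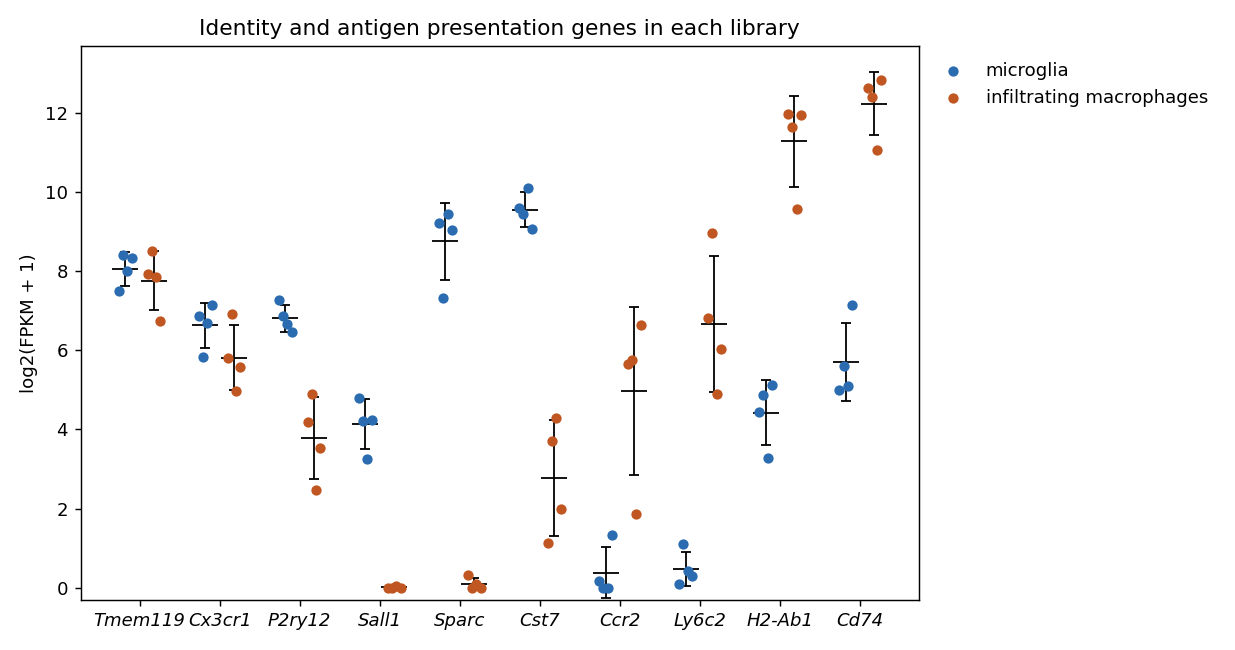
Log2(FPKM + 1) of 10 identity and antigen presentation genes, with 1 point per library, 4 of microglia (blue) and 4 of infiltrating macrophages (orange); bars mark the mean and SD of the log2 values. Tmem119 and Cx3cr1 overlap between the populations, while Sall1, Sparc and Cst7 are lower and Ccr2, Ly6c2, H2-Ab1 and Cd74 higher in all 4 macrophage libraries than in any microglial library.

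Of 23 tested markers of monocytes and monocyte-derived macrophages, 11 were called higher and 0 lower (17 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 2.45. Ccr2, the chemokine receptor that brings monocytes out of the bone marrow, averaged 51.0 ± 39.5 FPKM in macrophages and 0.417 ± 0.747 in microglia (4.60 ± 0.85 SE, adjusted p = 0.00251). Macrophage 7 stood at 2.64 FPKM of Ccr2, near the 1.53 of microglia 4, against 48.98, 52.95 and 99.41 in macrophages 5, 6 and 8. Ly6c2 was higher by 6.19 ± 0.73 (adjusted p = 1.07e-05), although reads shared with its near-identical neighbour Ly6c1, also called, leave the level of each uncertain. Tgfbi, an extracellular matrix protein, averaged 427 ± 207 against 49.8 ± 27.9 FPKM (adjusted p = 0.00192), and Crip1, a small LIM-domain protein, 186 ± 88.1 against 16.6 ± 10.8 (adjusted p = 0.00108). As a set the list was higher (camera adjusted p = 8.86e-13; adjusted p = 0.207 with an estimated correlation, the highest of 23 alternatives). The term for Y-linked expression left 2 members called at a list median of 2.16, with Ccr2 at 3.64, Tgfbi at 2.80 and Crip1 at 3.75 (none of them called; 4.60, 3.15 and 3.50 without the term), and the removal of microglia 2 and 3 left 9.

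Among other large differences, Plbd1, a lysosomal phospholipase B-like protein, averaged 123 ± 67.2 FPKM in macrophages and was listed at 0 in microglia 1, 2 and 3 and at 2.30 in microglia 4 (adjusted p = 4.41e-06). Acp5, tartrate-resistant acid phosphatase, averaged 128 ± 32.4 FPKM in macrophages against 0.0722, 0, 0.887 and 4.38 in microglia 1 to 4 (adjusted p = 1.26e-06). In the other direction, Ecscr, a cell surface protein first known from endothelium and 1 of the 7 called members of the microglial list, averaged 92.8 ± 55.7 FPKM in microglia and at most 1.28 in macrophages, and Ak1, adenylate kinase, 56.0 ± 20.4 and at most 1.8. Pmp22, a myelin membrane protein, averaged 117 ± 27.5 FPKM in microglia and 3.69 ± 3.06 in macrophages. The acute-phase gene Saa3 (40.5 ± 25.7 against at most 0.712) and Gpr84, a receptor for medium-chain fatty acids (77.8 ± 10.4 against 4.43 ± 4.84), were also lower in macrophages, with adjusted p = 0.000611 and 0.000291. With the term for Y-linked expression Acp5, Ecscr and Ak1 were called (adjusted p = 0.0479, 0.0143 and 0.0246), and Plbd1, Pmp22, Saa3 and Gpr84 were not (0.0637, 0.0689, 1 and 0.128). The log2 fold changes of these 4 were 4.93, -4.38, -2.48 and -4.48 with the term against 6.22, -4.86, -4.60 and -4.36 without it. For each of these 7 genes that was the highest adjusted p of the alternatives run, apart from the exact permutation test, and the lowest lay at 4.81e-06 or below.

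The class II genes of antigen presentation were the most strongly raised of the fixed lists by single members. H2-Ab1, the class II A beta chain on mouse chromosome 17 (34400172 to 34406363), averaged 2968 ± 1524 FPKM in macrophages and 22.8 ± 10.8 in microglia (6.85 ± 0.56 SE, adjusted p = 2.1e-08). H2-Aa, its alpha chain partner (17, 34419696 to 34424716), averaged 1710 ± 858 FPKM in macrophages against 9.39, 0, 2.71 and 17 in microglia 1 to 4, and H2-Eb1 (17, 34442812 to 34453619) 715 ± 349 against 3.99, 0, 0 and 13.8. With Cd74 (chromosome 18, 60963503 to 60972306), these were the 4 called members of 12 tested, with 0 lower (7 higher and 0 lower adjusted over the list alone). All 4 were called under each alternative run apart from the exact permutation test, the term for Y-linked expression included. H2-Ab1 was lowest in macrophage 7, at 754.5 FPKM against at least 3167 in the other 3. The dendritic cell genes Ccr7 and Ccl22, singled out after their values were seen and below the expression filter, were also low there: they were listed at 0 in microglia and stood at 15.8, 11.1, 0.165 and 62.4 FPKM and at 3.76, 23.9, 0.0779 and 17.6 FPKM in macrophages 5 to 8. The class II set was higher (camera adjusted p = 1.79e-12), a call lost with an estimated correlation (adjusted p = 0.207, the highest of 23 alternatives). Of 17 tested class I genes 0 were called by limma over all genes or adjusted over the list alone, with 3 at an unadjusted p below 0.05. B2m, the shared light chain, averaged 3082 ± 1337 FPKM in microglia and 1576 ± 740 in macrophages (adjusted p = 0.34). The class I set was not called (camera adjusted p = 0.765), but it was called higher with the term for Y-linked expression (adjusted p = 0.00349), after quantile normalization (0.00302) and without microglia 2 and 3 (0.049; range 0.00302 to 0.987 over 23 alternatives). With the term, none of its members was among the 19 genes called.

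Interferon response genes had mostly positive folds, 22 of 28 tested, with a median of 0.88, but 0 were called by limma over all genes or adjusted over the list alone, and 7 had an unadjusted p below 0.05. Bst2, the virion-tethering protein tetherin, averaged 407 ± 187 FPKM in microglia and 662 ± 449 in macrophages (adjusted p = 0.666). As a set the list was higher (camera adjusted p = 0.0173; 0.588 as the adjusted p with an estimated correlation, the highest of 23 alternatives), a call lost without microglia 1 (0.0769), microglia 4 (0.0757) or macrophage 6 (0.16). Of 20 pattern recognition genes, 4 were called higher and 0 lower (5 and 0 adjusted over the list alone). Clec4n, the fungal receptor dectin-2, averaged 63.8 ± 56.6 FPKM in macrophages against 4.36, 0, 0.759 and 0 in microglia 1 to 4 (adjusted p = 0.000377). Myd88, the adaptor of Toll-like receptors, averaged 49.9 ± 31.9 against 8.63 ± 6.84 (adjusted p = 0.0413), and the lectin receptor Clec4a2 15.9 ± 15.2 against 1.08 ± 1.79 (adjusted p = 0.0275). Both calls were lost without macrophage 5, 6 or 8 or microglia 3, and that of Myd88 also without microglia 2 and that of Clec4a2 also without microglia 1. The pattern recognition set was not called (camera adjusted p = 0.115), except without macrophage 5 (0.0457; range 0.0457 to 0.773 over 23 alternatives). With the term for Y-linked expression Clec4n was the pattern recognition gene called, and no member of the fixed interferon list was. That list does not hold every interferon-inducible gene. Ifi47, outside it, was called higher without the term (log2 fold change 3.30) and stood at 5.785 with the term.

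Genes known from injury-associated microglia went both ways. Of 23 tested, 4 were called lower in macrophages and 1 higher (12 and 4 adjusted over the list alone). Ctsd, the lysosomal protease cathepsin D, averaged 13220 ± 3072 FPKM in microglia and 3029 ± 1270 in macrophages (-2.20 ± 0.44 SE, adjusted p = 0.00464), and Cd9, a tetraspanin, 870 ± 149 against 179 ± 80.2 (adjusted p = 0.0042). Cst7 was lower by -6.78 ± 0.60 (adjusted p = 7.8e-08) and Timp2, an inhibitor of metalloproteinases, by -2.06 ± 0.52 (adjusted p = 0.032). The integrin Itgax (CD11c) was the member called higher, at 52.1 ± 10.6 FPKM in macrophages and 5.75 ± 4.05 in microglia (adjusted p = 0.00277). Apoe, the lipid carrier apolipoprotein E, averaged 11240 ± 3416 FPKM in macrophages and 4578 ± 2713 in microglia, a difference that did not pass (1.43 ± 0.47, adjusted p = 0.123; range 0.0062 to 1 over 25 alternatives). The set was lower (camera adjusted p = 1.86e-07, but adjusted p = 0.299 with an estimated correlation, the highest of 23 alternatives). With the term for Y-linked expression Cst7 was the member called. The log2 fold changes of Cst7, Ctsd and Cd9 were -6.285, -2.545 and -2.07 with it against -6.78, -2.20 and -2.40 without. Those of Timp2 and Itgax were -2.085 and 3.69 against -2.06 and 3.13.

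Lysosomal genes included 2 called lower and 0 higher among 24 tested, the same numbers over all genes and adjusted over the list alone. They were the proteases Ctsl, at 313 ± 81.1 FPKM in microglia and 55.4 ± 26.8 in macrophages (adjusted p = 0.00295), and Ctsf, at 30.1 ± 7.15 and 2.89 ± 1.37 (adjusted p = 0.00528). The lysosomal set was lower (camera adjusted p = 0.0023), a call lost with an estimated correlation (adjusted p = 0.573, the highest of 23 alternatives). Of 24 complement and phagocytosis genes, Cfb, the alternative-pathway factor B, was called higher, at 66.9 ± 33.9 FPKM against 2.32 ± 1.79 (4.47 ± 0.65 SE, adjusted p = 0.000187), and 0 lower. Adjusted over the list alone, 1 was higher and 2 lower. The set as a whole was lower (camera adjusted p = 1.65e-05; adjusted p = 0.342 with an estimated correlation, the highest of 23 alternatives), against the direction of its 1 called member. Among 16 lipid handling genes, 2 were called higher, Pla2g7 (41.0 ± 16.8 against 3.83, 0, 21.9 and 7.79 FPKM in microglia 1 to 4) and Pltp (15.1 ± 7.99 against 0.892, 0, 1.68 and 3.47), and 1 lower, the fatty acid binding protein Fabp3 (36.7 ± 17.5 FPKM in microglia, at most 3.23 in macrophages). The calls of Pla2g7 and Pltp were each lost without macrophage 5, 6 or 8 or microglia 1. The Pla2g7 call was lost also without microglia 2 or macrophage 7, and that of Pltp also without microglia 3. The lipid set was not called (camera adjusted p = 0.629), and the counts of its members were the same adjusted over the list alone. No lysosomal, complement or lipid gene was called with the term for Y-linked expression. The log2 fold changes of Ctsl, Ctsf and Cfb were -2.56, -3.38 and 3.72 with it against -2.54, -3.03 and 4.47 without. Those of Fabp3, Pla2g7 and Pltp were -3.36, 2.15 and 1.70 against -3.90, 2.81 and 2.74.

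Among 19 inflammatory cytokine genes, the chemokines Ccl4 and Ccl3 were called lower in macrophages and 0 higher (3 lower and 3 higher adjusted over the list alone). Ccl4 averaged 768 ± 220 FPKM in microglia and 154 ± 112 in macrophages (-2.52 ± 0.50 SE, adjusted p = 0.00455), and Ccl3 321 ± 73.0 against 88.0 ± 60.3 (adjusted p = 0.0233), a call lost without microglia 1, 2 or 3 or macrophage 5, 7 or 8. The set was called lower (camera adjusted p = 0.0484) although its median log2 fold change was 0.03 and its mean -0.11. That call was lost with an estimated correlation (adjusted p = 0.588), with the term for Y-linked expression (0.911, the highest of 23 alternatives) and without microglia 2 (0.789) or macrophage 5 (0.108), 7 (0.0536) or 8 (0.122). Of 11 tested genes of alternative activation, 2 were called higher and 0 lower (6 and 0 adjusted over the list alone). They were the C-type lectins Mgl2, at 31.2 ± 16.5 FPKM against 0.0774 ± 0.0550 (4.70 ± 0.69, adjusted p = 0.000219), and Clec10a, listed at 0 in every microglial library and at 10.1, 16.9, 1.63 and 11.1 FPKM in macrophages 5 to 8 (adjusted p = 0.00591). The alternative activation set was higher (camera adjusted p = 0.00148; adjusted p = 0.342 with an estimated correlation, the highest of 23 alternatives). No member of either list was called with the term for Y-linked expression. The log2 fold changes of Ccl4, Ccl3 and Mgl2 were -2.37, -1.56 and 4.73 with it against -2.52, -2.02 and 4.70 without. That of Clec10a, at 0 in every microglial library, cannot change with the term.

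Adhesion and migration genes had 2 of 17 called higher and 0 lower (5 and 1 adjusted over the list alone). The chemokine receptor Ccr1 averaged 98.6 ± 60.2 FPKM in macrophages and 2.97 ± 2.66 in microglia (adjusted p = 9.74e-05), and the homing integrin subunit Itgb7 20.6 ± 14.5 against 0.202 in microglia 1 and 0 in microglia 2, 3 and 4 (adjusted p = 0.00241). The set was higher (camera adjusted p = 0.0131; adjusted p = 0.495 with an estimated correlation, the highest of 23 alternatives, and 0.14 with the term for Y-linked expression). Of 12 matrix remodelling genes, Anxa1, the anti-inflammatory annexin A1, and Mmp14, a membrane-anchored metalloproteinase, were called higher (37.6 ± 23.4 FPKM against 0.139, 0, 0.342 and 0.154 in microglia 1 to 4, and 57.6 ± 29.6 against 8.68 ± 8.14). Serpine2, a serine protease inhibitor, was called lower (6.62 ± 7.79 against 174 ± 132 FPKM, adjusted p = 0.000225). Adjusted over the list alone, 3 matrix genes were higher and 2 lower, and the set was not called (camera adjusted p = 0.919). The call of Mmp14 was lost without microglia 3 or macrophage 5, 6 or 8. Of 25 transcription factors, Runx3, a Runt-domain factor, was called higher (20.8 ± 7.10 against 0.419 ± 0.702 FPKM, adjusted p = 0.000948). So were Gdf15 among 9 growth factors (4.49 ± 1.67 FPKM in macrophages, 0.810 in microglia 3 and 0 in the rest; adjusted p = 0.0247) and the ecto-nucleotidase Nt5e among 8 purinergic genes (2.42 ± 0.263 against 0.0492, 0, 0.302 and 0.0543; adjusted p = 0.0484). Those 3 lists had 0 called lower, gave the same counts adjusted over the list alone and were not called as sets (camera adjusted p = 0.989, 0.947 and 0.99). The Nt5e call was lost without any 1 of the 8 libraries and that of Gdf15 without microglia 1 or 4 or macrophage 5 or 8. With the term for Y-linked expression, Serpine2 alone was called among the genes of these 5 lists.

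Of 24 tested heat-shock and immediate early genes, the inducible Hsp70 genes Hspa1b and Hspa1a were called higher and 0 lower (9 and 0 adjusted over the list alone), and 23 of 24 had a positive fold, with a median of 1.28. Hspa1b averaged 247 ± 206 FPKM in macrophages and 5.08 ± 4.93 in microglia (5.31 ± 0.71 SE, adjusted p = 5.72e-05), and Hspa1a 215 ± 201 against 7.06 ± 2.79 (4.28 ± 0.64, adjusted p = 0.000268). The 2 genes are near-identical and adjacent on chromosome 17, so the level of each is uncertain. The set was higher (camera adjusted p = 3.7e-05; adjusted p = 0.379 with an estimated correlation, the highest of 23 alternatives). In the cell cycle list 25 of 26 tested genes had a positive fold, 1 was called higher and 0 lower (3 and 0 adjusted over the list alone). This was Bub1b, a spindle checkpoint kinase, at 8.27 ± 3.33 against 0.701 ± 1.10 FPKM (adjusted p = 0.0374), a call lost without microglia 1 or 3 or macrophage 5, 6 or 8. Without microglia 2 and 3 the median of the cell cycle list fell from 1.31 to 0.64 and 0 members were called. Over all tested genes the median fell from 0.37 to 0.17. The cell cycle set was higher (camera adjusted p = 1.65e-05; adjusted p = 0.438 with an estimated correlation, the highest of 23 alternatives, and 0.093 with the term for Y-linked expression). No gene of either list was called with that term. The log2 fold changes of Hspa1b, Hspa1a and Bub1b were 3.81, 3.70 and 1.395 with it against 5.31, 4.28 and 2.55 without.

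Metabolic and ribosomal genes lay slightly below the other genes in macrophages, with 0 calls by limma over all genes or adjusted over each list alone. An unadjusted p below 0.05 was found for 4 of 76 oxidative phosphorylation genes, 1 of 80 ribosomal and 1 of 19 glycolysis genes. Aldoa, the glycolytic aldolase, averaged 1004 ± 493 FPKM in microglia and 424 ± 287 in macrophages (adjusted p = 0.182, but 0.0288 without macrophage 6; range 0.0253 to 1 over 25 alternatives). Cox6a1, a cytochrome c oxidase subunit, averaged 747 ± 301 against 487 ± 337 (adjusted p = 0.479), and Rpl41, a ribosomal protein, 1931 ± 1014 against 1184 ± 621 (adjusted p = 0.496). All 3 sets were called lower by camera, oxidative phosphorylation (median log2 fold change minus that of all tested genes -0.81; adjusted p = 4.6e-08), ribosomal proteins (-0.53; adjusted p = 0.000413) and glycolysis (-0.53; adjusted p = 0.0196). None of the calls held with an estimated correlation (adjusted p = 0.569, 0.722 and 0.573). The ribosomal set turned to higher with the term for Y-linked expression (adjusted p = 0.0157), after quantile normalization (0.333) and without microglia 2 and 3 (0.949; range 1.77e-07 to 0.949 over 23 alternatives). It was not called without microglia 3 (0.125), and the glycolysis call was lost without microglia 1 (0.0509) or macrophage 8 (0.0798). The oxidative phosphorylation call was lost with the term for Y-linked expression (adjusted p = 0.103; range 2.48e-16 to 0.57), and no gene of the 3 lists was among the 19 called with it.

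**Figure D3:**
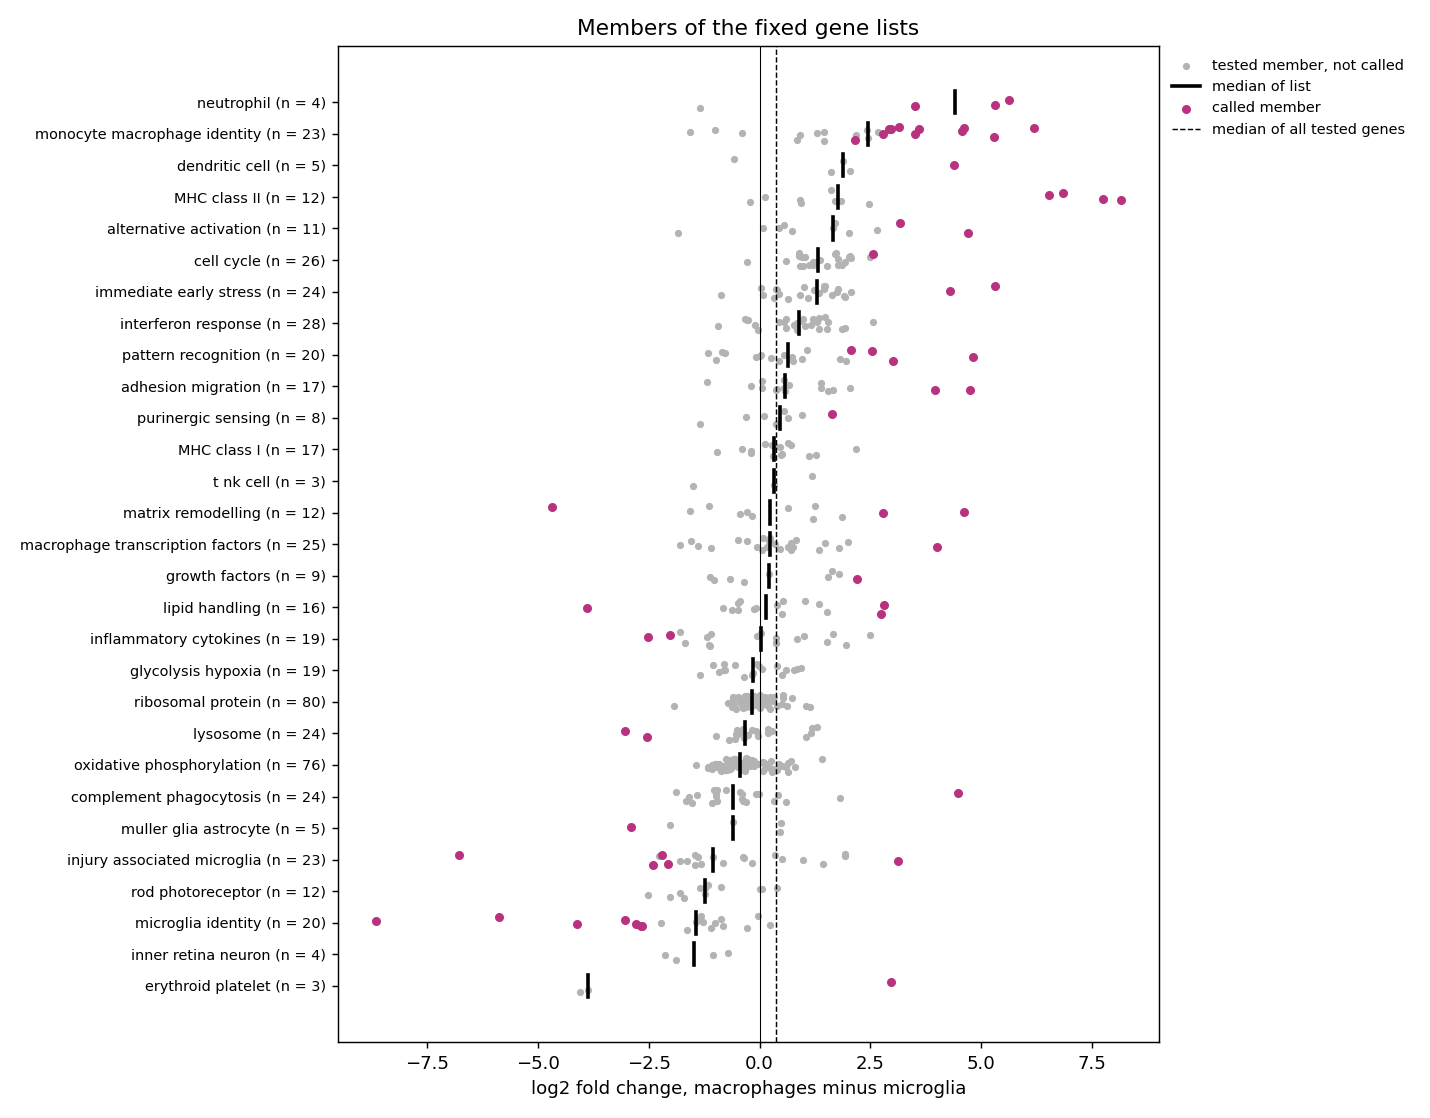
Log2 fold change (macrophages minus microglia, log2(FPKM + 1) scale) of the tested members of each gene list with 3 or more tested, 1 point per gene, called members in colour; n is the number tested. Black bars mark list medians, from 4.40 for neutrophil genes to -3.88 for erythroid and platelet genes, and the dashed line the median of all tested genes, 0.37.

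Genes listed in advance for other cell types were unevenly spread over the populations, and bulk libraries do not show which cells held them. The neutrophil genes S100a8 and S100a9, which encode the subunits of calprotectin, were listed at 0 in every microglial library and stood at 22, 92.0, 67.4 and 38.6 FPKM and at 18.3, 81.9, 50.2 and 28.8 FPKM in macrophages 5 to 8 (adjusted p = 1.28e-05 and 3.61e-05). Retnlg, a neutrophil resistin-like protein, was at 0 in microglia and at 1.06, 61.3, 18.8 and 5.57 FPKM in macrophages (adjusted p = 0.0163), a call lost without macrophage 6. These were the 3 called of 4 tested (3 higher and 1 lower adjusted over the list alone), and the set was higher (camera adjusted p = 0.00026; adjusted p = 0.207 with an estimated correlation, the highest of 23 alternatives). S100a8 and S100a9 stayed called with the term for Y-linked expression and Retnlg did not. These genes were at 0 in every microglial library, so the term cannot change their log2 fold changes. Their unchanged folds therefore say nothing about the split of the microglial libraries. Of 5 dendritic cell genes, the chemokine Ccl17 was called higher, at 48.0, 97.5, 1.07 and 20.4 FPKM in macrophages 5 to 8 and at most 0.164 in microglia (adjusted p = 0.00575; 3 higher and 0 lower adjusted over the list alone), a call lost without macrophage 6 and with the term for Y-linked expression (0.555, the highest of 24 alternatives; log2 fold change 4.43 against 4.37). That set was higher (camera adjusted p = 0.0226; adjusted p = 0.438 with an estimated correlation, the highest of 22 alternatives), a call lost without microglia 1 (0.0655), microglia 4 (0.0596) or macrophage 8 (0.0502). In the erythroid and platelet list 1 of 3 tested was called, the platelet factor Pf4 (35.1 ± 29.4 against 15.1, 0, 2.12 and 3.09 FPKM in microglia 1 to 4; adjusted p = 0.0374), which lost its call without microglia 2, 3 or 4 or any 1 macrophage library. The set was not called (camera adjusted p = 0.0974), but was lower without microglia 4 (0.00132) and higher with the term for Y-linked expression (0.0391; range 0.00132 to 0.676 over 22 alternatives). Adjusted over the list alone, 1 was higher and 2 lower, and with the term for Y-linked expression Pf4 was not called (adjusted p = 1, the highest of 25 alternatives; 2.85 against 2.96).

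The fixed lists of Müller glia, rod and inner retina genes stood higher in the microglial libraries as sets, with 1 of their genes called. Slc1a3, the glial glutamate transporter, averaged 10.4 ± 6.23 FPKM in microglia and at most 1.20 in macrophages (-2.90 ± 0.66 SE, adjusted p = 0.0165), 1 of 5 tested genes of Müller glia and astrocytes (0 higher and 2 lower adjusted over the list alone). Its call was lost without macrophage 5, 6 or 8 and with the term for Y-linked expression (adjusted p = 1, the highest of 24 alternatives; log2 fold change -2.55). The Müller glia set was lower in macrophages (camera adjusted p = 0.00418; adjusted p = 0.207 with an estimated correlation; range 0.000948 to 0.337 over 22 alternatives), a call lost without microglia 2 (0.101), without microglia 2 and 3 (0.337, with a positive list median of 0.14), without microglia 2 and macrophage 7 (0.0592) and with the term for Y-linked expression (0.0987). Among 12 tested rod genes 0 were called by limma over all genes or adjusted over the list alone and 4 had an unadjusted p below 0.05. Of the 12, 9 had a negative and 3 a positive fold, and the set was lower (median -1.23, camera adjusted p = 1.01e-05; adjusted p = 0.299 with an estimated correlation, the highest of 23 alternatives). The most abundant of them, Gnb1, a G protein subunit that many cells express, averaged 47.0 ± 5.34 FPKM in microglia and 53.3 ± 32.6 in macrophages (adjusted p = 0.991). The inner retina set was also lower (4 tested, 0 called by limma, 2 at an unadjusted p below 0.05, 1 lower adjusted over the list alone, median -1.47, camera adjusted p = 0.000825; adjusted p = 0.158 with an estimated correlation, the highest of 22 alternatives). Pcp2, a bipolar cell gene, stood at 1.13, 0, 53.3 and 5.61 FPKM in microglia 1 to 4 and at most 1.61 in macrophages (adjusted p = 0.3). T and NK cell genes had 0 of 3 tested called by limma, 0 at an unadjusted p below 0.05 (Trat1 at 0.862, 23.7, 6.14 and 2.95 FPKM in microglia, adjusted p = 0.352; set adjusted p = 0.765). The B cell list had 1 tested member, Cd79b (adjusted p = 0.941), and the endothelial and pericyte list 2, with Acta2 at 8.65 ± 4.67 against 6.05 ± 1.86 FPKM (adjusted p = 0.828). Both lists were too small for a set test. No gene of the retinal, T and NK cell, B cell or endothelial lists was among the 19 called with the term for Y-linked expression, and no cone photoreceptor or pigment epithelium gene passed the expression filter.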

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

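The tests below of microglia 4 against both populations were set before their result was seen; the split count, the fit with a term for Y-linked expression and the tests of Tmem119 and of the Ifi200 genes were chosen after the results were seen, as was the choice of these 3 patterns over the neutrophil genes, the heat-shock genes and the excess of higher calls.

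The first pattern is the set of 219 called genes against the animals behind the libraries. Of the 35 ways to split the 8 libraries into 4 and 4, 1 (the real split) gave as many calls and the highest other gave 13. That is the smallest share 35 splits allow, and it treats the libraries as independent, which the labels do not state. The count was also chosen after the calls were seen, so it does not exclude chance. A difference between the animals of microglia 1 to 3 and all other libraries, read from Y-linked and haemoglobin transcripts, cannot be told apart from cell population, since 19 of the genes stayed called with a term for it but that fit rests on microglia 4 alone. Of 237 genes called without microglia 4, that library was nearer to the microglial mean in 157 (66.2%), between the 25% and 75% that would have decided, at a median position of 0.29 on a scale from 0 (microglia) to 1 (macrophages). These genes were picked for a large difference in microglia 1 to 3, which by itself moves a left-out library toward the macrophages. No other microglial library was left out for reference, so the share decides nothing. By Xist and Y-linked transcripts, microglia 1 to 3 read as male, and microglia 4 and the macrophage libraries as female. Sex is therefore confounded with cell population apart from microglia 4, and the labels do not give it. Pooling and blood in the tissue remain open and are not in the labels.

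The second pattern is Tmem119, which stood at 38.9%, 134%, 84.3% and 88.8% of its microglial mean in macrophages 8, 6, 7 and 5. Microglial cells or RNA in the macrophage libraries would bring the other abundant microglial transcripts along, yet Sall1 and Sparc reached at most 0.198% of their microglial mean in any macrophage library. Over the 20 tested microglial markers the median was 37.4%, with 5 below 10% and 6 above 50%. Expression of Tmem119 by infiltrating macrophages themselves is therefore a hypothesis that these values leave standing, and it was not tested on single cells.

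The third pattern is on chromosome 1 (mm9, 175350735 to 175961886), where Ifi202b was lower in macrophages by -3.98 ± 0.73 SE (27.9 ± 23 FPKM in microglia; 0.466, 0, 2.21 and 0 in macrophages 5 to 8; limma adjusted p = 0.0022) and 6 of its 8 tested neighbours of the Ifi200 group were higher, among them Mndal by 3.78 (adjusted p = 0.0011); with the term for Y-linked expression none of these 7 was called, with Ifi202b at -3.88 and Mndal at 3.995. The fall of Ifi202b, an interferon-inducible gene, is opposite to the rise that a stronger interferon response would give. That direction is the pattern itself, and no separate test was run. For the neighbours a stronger interferon response stays open. Their median of 2.74 exceeds the 0.85 of the other 27 interferon genes, whose upper quartile is 1.32. Yet the whole list was called as a set (camera adjusted p = 0.0173, though 0.588 with an estimated correlation, the highest of 23 alternatives, and 0.186 by fry). Reads shared between these near-identical genes also stay open: the summed FPKM of the 9 genes was 3.17 times higher in macrophages, yet macrophage 6 stood at 599.9 and the populations overlapped, with 179 in microglia 2 and 174 in macrophage 7. A strain variant is a further candidate explanation on this mixed background and was not tested, as sequence variants are not analysed here.

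In 15 of 134 sets of 4 libraries, 1 library stood apart from the other 3 by the Dixon test, where chance gives about 1 in 20, or 6.7; in 6 of the 15 the other 3 libraries were at 0, where any value above 0 passes that test, which leaves 9. Microglia 4 was high in Ccr2 (1.53 FPKM; others at most 0.131), Plbd1 (2.30; others 0), Bub1b (2.34; others at most 0.216) and Runx3 (1.47; others at most 0.161), each a gene called higher in macrophages. Macrophage 7 was low in H2-Ab1 (754.5 FPKM; others at least 3167) and Anxa1 (4.20; others at least 41.5) and was the 1 macrophage library with a value for Sall1 (0.0352; others 0). Macrophage 6 was high in Ccl3 (178.4 FPKM; others at most 60.7) and Clec4a2 (38.7; others at most 8.70) and was listed at 0 for Trat1 (others at least 1.54). Microglia 2 was high in Aldoa (1742 FPKM; others at most 798.6). Against 0 in the other libraries of their population, Ak1 stood at 1.8 FPKM in macrophage 5, Itgb7 at 0.202 in microglia 1, Gdf15 at 0.810 in microglia 3 and Ccl17 at 0.164 in microglia 3.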

How the results depend on the processing

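The fits with a term for Y-linked expression, without pairs of libraries, without small RNA and LOWDATA symbols and with failed symbols kept were chosen after seeing the data. Of the 65 named genes, 52 were called. These kept their sign under every alternative, and 12 were called in each one apart from the exact permutation test. Single left-out libraries ended 14 of the 52 calls in at least 1 case; the term for Y-linked expression ended 38, no filter 31, the fit without microglia 2 and 3 ended 11 and a pseudocount of 0.1 ended 10. Library weights called 4 further named genes, quantile normalization 2 and upper-quartile scaling 1. The 219 calls (154 higher, 65 lower) ranged from 119 to 258 when single libraries were left out (78 to 198 higher, 35 to 81 lower). They became 136 with a pseudocount of 0.1 (87 higher), 50 without a low-value filter (30 higher, 20 lower, with 20454 genes sharing the adjustment) and 132 with a filter of 5 FPKM (82 higher, 5283 genes tested). The lower calls rose to 111 (upper quartile), 110 (median of ratios) and 149 (quantile). Library weights, from 0.254 for microglia 2 to 6.18 for macrophage 5, called 1075 (744 higher, 331 lower). The term for Y-linked expression called 19 (14 higher, 5 lower). It leaves microglia 4 alone against the macrophages, which lowers power. Microglia 4 enters the fold with and without the term, and a gene at 0 in every microglial library keeps its fold. Similar folds therefore do not separate low power from the split of the microglial libraries. Of the 38 named calls lost there, 33 had a log2 fold change within 1.5 times that without the term and 5 a smaller one (Saa3, Clec4a2, Myd88, Bub1b and Pltp). Exact permutation called 0 (0 higher, 0 lower), with 714 genes at an unadjusted p below 0.05 and a smallest adjusted p of 0.374, so it could not pass the threshold here. Of the 20 called gene lists, 0 were called with an estimated correlation and 5 by fry. Under scaling, calls were lost for the inflammatory list (upper quartile, median of ratios and quantile), the lysosomal and glycolysis lists (quantile) and the dendritic list (upper quartile and equal sums). A pseudocount of 0.1 or no filter also ended the inflammatory and dendritic calls, and a filter of 5 FPKM those of adhesion and alternative activation. Without microglia 2 and macrophage 7 the inflammatory, glycolysis and Müller glia calls ended, and without microglia 2 and 3 the inflammatory and Müller glia calls. The class I list became called in 3 alternatives, as did the erythroid and platelet list. The ribosomal list (lower, adjusted p = 0.000413) turned to higher at 0.333 after quantile normalization, 0.949 without microglia 2 and 3 and 0.0157 with the term for Y-linked expression. Where no reason is given, the cause was not tested. No paired analysis was possible because the 2 populations share no replicate number. In simulated data 0.8% of changes of 1 on the log2 scale were found, and the smallest called difference was 1.55, so genes below the threshold are not shown to be equal. Depth limits low genes; how far was not compared between libraries.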

Other observations

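Gene families were counted after the calls had been seen, with families formed by symbol stem, some set by hand (S100a, Ms4a, Ly6, H2-, Cd300, Ctla2, Clec and the Ifi200 group), so their p-values are not independent of the calls. Among 276 families with at least 5 tested genes, 8 held more called genes than the background of all tested genes (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p below 0.05), of which 7 are described here. The Ifi200 group had 7 of 9 called (adjusted p = 3.35e-08). C-type lectin receptors (Clec) had 5 of 14 called, all higher in macrophages (adjusted p = 0.00104): Clec4n, Clec10a, Clec12a, Clec4d and Clec4a2. The Ms4a membrane proteins had 3 of 7 called higher (Ms4a4c, Ms4a6b and Ms4a4b, adjusted p = 0.0228), the Ly6 antigens 3 of 5 (Ly6c2, Ly6c1 and Ly6a, 0.00844) and the S100a calcium-binding proteins 3 of 9 (S100a8, S100a9 and S100a11, 0.0378). Chemokines of the Ccl family were called in both directions, with Ccl17 higher and Ccl3 and Ccl4 lower (3 of 10, 0.0464). The snoRNAs (Snord) had 3 of 8 called higher (0.0299), but FPKM of such short RNAs inside host genes is unstable. With the term for Y-linked expression, 5 genes of these 7 families were called: Clec4n, Ly6c2, S100a8, S100a9 and 1 snoRNA.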
